A study of Mus musculus with 6 samples.

How the data were processed

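Primary hepatocytes of Bl6/N mice were profiled by paired-end sequencing of polyA RNA in 6 libraries, 3 Control and 3 TNF. Per the labels' protocols, 400000 cells were plated per well and kept for 16 h in a starvation medium with 5 mM glucose. They were then treated for 8 h with 1 µM corticosterone, a ligand of the glucocorticoid receptor (GR), and 10 µM WY-14643, a ligand of the nuclear receptor PPARα. Vehicle (Control) or 1 ng/ml TNF was added at the same time. Libraries were made from 500 ng of total RNA with the NEBNext Ultra RNA kit. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate animals or cultures, so the spread between these samples, on which p-values draw, may be technical.

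Reads were aligned with STAR 2.6.1a to the mouse genome build mm10, per the submitters' processing notes. The counting program, annotation release and strand setting are not given in the sources used here. The deposited table held 19764 genes, with 1 row per symbol and a RefSeq identifier, and its per-library values were log2 CPM (read counts scaled to library size) with a prior count added by the authors. The authors' deposited table also gave a log2 fold change, a likelihood ratio score, a p-value and an adjusted p-value per gene; the model behind them and the adjustment method are not given in the sources used here. Coordinates are those of the table, shown from base 1. Of its symbols, 19135 (96.8%) were found in GENCODE mouse release 21, and 19127 of these lay on the same chromosome. The counted length equalled the whole gene span in 85.0% of genes and was shorter in 2970, so reads were counted over introns as well as exons. Intronic and exonic reads were not separate in the values used here, and the 2 planned intron comparisons were not analysed here. Stretches where genes overlap were left out of the counted lengths. This left Abcg5 and Abcg8, Cxcl16 and Zmynd15, Nfkb2 and Psd, Nr1i3 and Tomm40l, and Sirt3 and Ric8 partly uncounted. The same holds for Slc16a6 and Arsg, Stab1 and Nt5dc2, Fosl1 and Ccdc85b, and Ncor1 and Ttc19. Overlap does not account for all uncounted length. Slc16a6 lost 2727 bases against an overlap of 223. With no overlapping gene among the 19764, Nfkbia was counted over 1341 of 3239 bases and Ahsg over 5065 of 7437. Pkhd1, also without an overlap, lost 35847 bases. The reason is not known here.

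The deposited log2 values shared a floor of -3.35 (0.098 CPM). After the floor was subtracted on the linear scale, 100.0% of the 118584 values were whole multiples of a step per library, within a tolerance of 1e-06 reads, so whole reads were recovered. Library totals lay between 17612060 and 25114289 reads. The authors' scaling, read from the steps, differed from the totals by factors of 0.963 to 1.03 and was kept. A gene with 3 reads, the upper limit that a count of 0 allows, corresponds to 0.124 to 0.166 CPM. Such limits cover counting error only.

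The test fixed before the data were examined was a count model for raw counts, with limma-trend on log2(value + 1) for normalized values. As the deposited unit was log2, limma 3.58.1 in R 4.3.3 was used on log2(CPM + 1) with a trended prior variance, group as the only term, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The planned quasi-likelihood and Wald count tests were not run, and limma-voom on the recovered reads was run in their place. Genes needed 10 reads, scaled to the median library, in 3 libraries and 15 reads in total. This left 12293 genes, and 7471 were not tested. Fold changes are on the log2(CPM + 1) scale, which understates changes of low genes.

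Control and TNF libraries shared replicate numbers, so a fit with the replicate number as a block was planned as an alternative. Deviations from the group means correlated across genes at 0.78, 0.79 and 0.79 for the same-numbered libraries, and between -0.47 and -0.34 for the others. Deviations cancel out within each group by construction, so the negative values follow largely from the positive ones. By the rule set in advance the numbers pair the samples. The pairing comes from the numbers in the titles and from these values, as the labels name no shared day or animal. The blocked fit called 2530 genes and the unpaired fit 53, so blocked values stand beside the unpaired ones. SEs of the blocked fit leaned on the prior variance shared between genes. For Ccl2 the blocked SE was 0.130, although its changes in the 3 pairs had an SD of 0.554. Blocked p-values therefore do not measure a gene's own spread between pairs alone. No libraries were duplicates: chi-square per degree of freedom between libraries lay between 14.9 and 41.7.

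Before the data were examined, 26 gene lists were fixed, and those with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. An estimated correlation and limma's fry, which asks whether a list's genes move on balance in a direction, were alternatives. Lists share members: the NF-κB and chemokine lists share 11, the GR and gluconeogenesis lists 7, the NF-κB and TNF receptor lists 5, and the PPARα and ketogenesis lists 3. The rule for named genes took a fixed set, then up to 12 largest rises and 12 largest falls past the threshold with a mean of at least 5 CPM and no overlap between groups, and then the 4 members of smallest p in each list. Of the genes it named, 116 were tested, and 2 of these are not reported here. Alternatives were other scalings, filters and pseudocounts (0.1 and 5), a fold change of 1.5 or more, voom, the block, and leaving out each library.

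The code was tested on simulated counts for the 12293 genes of the TNF against Control comparison, drawn 10 times, over 2 seeds, with 200 changed genes each. Their spread was that of the blocked fit's residuals, with count sampling added on top although the residuals already hold it. Each replicate number kept its real mean offset, so the simulated libraries were paired by construction. The gap between the fits was therefore built in and does not compare them independently. The unpaired fit recovered 0% of genes changed 1.25-fold, 26.4% of those changed 1.5-fold, 61.8% of those changed 2-fold and 93.4% of those changed 4-fold. The blocked fit recovered 49.4%, 75.6%, 92.0% and 100.0%. Of its 2530 real calls 280 were of 1.5-fold or more. Of the simulated calls, 0% in the unpaired and 7.63% in the blocked fit fell on unchanged genes, so the blocked fit's error rate was above the nominal level there. With a list of 20 genes shifted by 0.5 (log2), camera called the list in 20 of 20 draws at an unadjusted p under 0.05. That threshold is looser than the adjusted p used for the real lists. At that threshold camera called an unshifted list in 1 of 20 draws. These list genes were drawn at random with independent counts. The rates therefore do not show the error for lists whose members move together. In the real data the estimated unpaired correlation was 0.248 for the PPARα list and 0.0136 for the NF-κB list. For the chemokine list it was -0.00826, yet its camera adjusted p went from 1.40e-08 to 0.0341 with the estimate. Weaker p-values under that option therefore do not come from the correlation alone. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.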

Results

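The effect of TNF, a cytokine of inflammation, was measured in primary mouse hepatocytes held in a starvation-like state by corticosterone and WY-14643. Transcript levels were compared after 8 h between 3 TNF and 3 vehicle (Control) libraries. Control 1, 2 and 3 held 17612060, 25114289 and 20472187 reads over genes, and TNF 1, 2 and 3 held 20279611, 19295492 and 20051340. Levels are CPM as mean ± SD of 3 libraries, and changes are log2 differences of TNF minus Control. "Unpaired" denotes the limma fit without a block and "blocked" the limma fit with the replicate number as a block. "Rose" and "fell" are used of genes past an adjusted p of 0.05 in the blocked fit. SEs given below beside a gene's log2 change are those of the unpaired fit. Camera values for TNF against Control are also of the unpaired fit unless the block is named, while list counts of genes that rose or fell are blocked.

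Inflammatory mediators and NF-κB pathway genes were higher with TNF, and single metabolic genes such as Cyp4a10 and Cyp8b1 were lower. The chemokine Ccl2 rose from 14.8 ± 7.92 to 210 ± 56.8 CPM (log2 3.83, SE 0.35), and Icam1, a leukocyte adhesion molecule, from 44.7 ± 7.81 to 173 ± 24.2 CPM. Among genes that fell, the fatty acid ω-hydroxylase Cyp4a10 went from 27.5 ± 7.55 to 5.77 ± 2.59 CPM (log2 -2.11, SE 0.29). Cyp8b1, the sterol 12α-hydroxylase of bile acid synthesis, went from 21.7 ± 1.44 to 7.74 ± 1.89 CPM. The unpaired limma fit called 53 of 12293 genes, 44 higher and 9 lower. The blocked fit called 2530, 1156 higher and 1374 lower, including each of the 53; 160 of its calls were higher and 120 lower by 1.5-fold or more. Under median-of-ratios scaling the blocked fit called 1290 higher and 1282 lower. The unpaired count was 31, 11 and 10 without Control 1, 2 and 3, and 19, 9 and 20 without TNF 1, 2 and 3. The blocked count of lower genes was 907 without replicate 2.

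The 12 largest unpaired rises were led, in log2, by Ccl2 (3.83), the kinase Ikbke (2.25), the ubiquitin ligase Neurl3 (2.18) and the chemokine Cxcl1 (2.14). Icam1 (1.94), the receptor Tlr2 (1.82), Plscr1 (1.77), the NF-κB inhibitor Tnfaip3 (1.74) and Irak3 (1.69) came next. The others were D17H6S56E-5 (1.58), the chemokine Cxcl16 (1.47) and the NF-κB subunit Relb (1.39). The 9 falls were Cyp4a10 (-2.11), Cyp8b1 (-1.40), the sterol exporters Abcg5 (-1.29) and Abcg8 (-0.94), the aldehyde oxidase Aox3 (-1.10), the mitochondrial carrier Slc25a47 (-0.79), the sulfotransferase Sult1d1 (-0.62), the receptor Erbb3 (-0.58) and Mettl7a1 (-0.55). Limma's unpaired adjusted p was lowest for Ikbke (0.00432) and was 0.0106 for Ccl2, 0.0371 for Cyp4a10 and 0.0229 for Cyp8b1. Of 27 named genes past the unpaired threshold, Ikbke, Icam1, Tlr2, Plscr1, Relb and Nfkb2 stayed past it whichever single library was left out. Tnfaip3, Irak3, Abcg5, Abcg8, Slc25a47, Erbb3, Mettl7a1, Tapbp and Trp53 were lost from the unpaired calls whichever library was left out. In the blocked fit each of these stayed past the threshold whichever pair was left out. The same held for 83 of the 93 named genes past the blocked threshold. Cyp4a10 belongs to a cluster of similar genes, so its value is uncertain where reads can be shared. Abcg5 and Abcg8 overlap by 6622 bases, a stretch left out of the counted length of both.

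Ccl2 lies on chromosome 11 (mm10, 82035577 to 82037452), Icam1 on chromosome 9 (21015960 to 21028796), Cyp4a10 on chromosome 4 (115518287 to 115533649) and Cyp8b1 on chromosome 9 (121914356 to 121916305). Each was counted over its whole span.

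**Figure D1:**
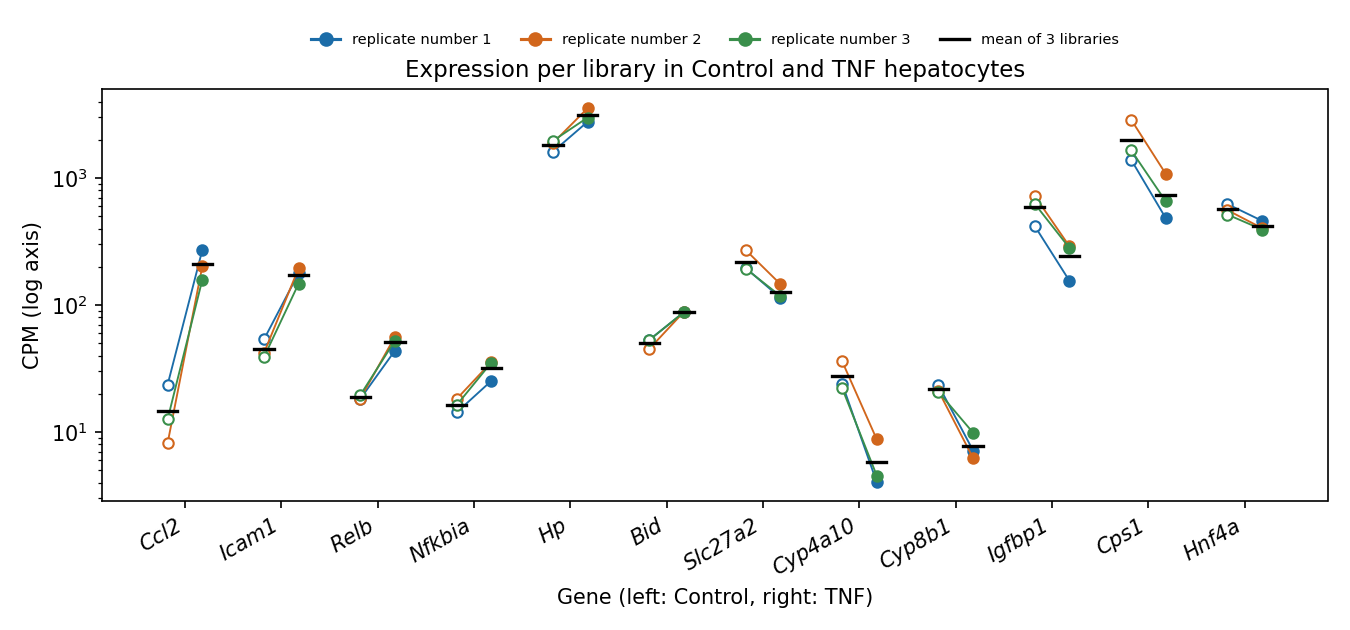
CPM on a log axis of 12 genes in each library, with Control as open and TNF as filled circles, same-numbered libraries joined by lines and black bars at the means of 3 libraries. In Ccl2 the mean went from 14.8 to 210 CPM, and in Cps1 from 1975 to 737 CPM, with the lines of the 3 pairs sloping the same way.

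NF-κB and TNF response genes rose almost as a group. Of 29 tested members, 28 rose in the blocked fit and none fell (29 rose when adjusted over the list alone). In the unpaired fit 13 were higher, and 25 when adjusted over the list alone. Examples are Nfkb2 (log2 1.36), Nfkbia, which encodes the inhibitor IκBα (16.2 ± 1.98 to 32.0 ± 5.83 CPM, log2 0.93), and Birc3, an inhibitor of apoptosis (log2 0.90). Nfkbia had an adjusted p of 0.0731 unpaired and 6.32e-07 blocked in limma. The list median was 0.71, and 0.74, 0.77 and 0.69 in the 3 pairs; camera gave an adjusted p of 3.23e-43. With an estimated correlation the adjusted p was 0.00413 unpaired and 0.166 blocked.

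Among chemokines and cytokines 10 of 16 tested genes rose and none fell (11 when adjusted over the list alone), with 3 higher in the unpaired fit. Ccl2 and Cxcl1 led, and Ccl9 rose by 0.53. The list had a camera adjusted p of 1.40e-08, which was 0.0341 with an estimated correlation unpaired and 0.166 with the block. Tnf itself had 2 reads over the 6 libraries, all in Control 3, and was not tested.

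Of 33 tested members of the interferon response and antigen presentation list, 12 rose, 2 fell and 19 did not pass the test (13 rose and 2 fell when adjusted over the list alone); the unpaired fit called 2. The immunoproteasome subunit Psmb10 rose by 0.93 (26.2 ± 2.76 to 50.7 ± 2.28 CPM), Tapbp, which loads peptides on MHC class I, by 0.57, and the guanylate-binding proteins Gbp2 and Gbp3 by 1.08 and 1.01. Gbp2 and Gbp3 have close paralogs that may share reads. By camera the adjusted p was 4.95e-06 (adjusted p = 0.271 with an estimated correlation).

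Of 28 TNF receptor signalling genes 10 rose and 1 fell (11 and 1 when adjusted over the list alone). Without replicate 2, 8 were higher and 2 lower. Traf2 (0.31) and the receptor gene Tnfrsf1b (0.28) were among those that rose. The adjusted p by camera was 5.34e-05, and 0.211 with an estimated correlation. Of 23 apoptosis and survival genes 9 rose and 4 fell (11 and 6 when adjusted over the list alone), including the death-signalling genes Bid (0.80), Trp53 (0.43) and Fas (0.72). The lower members numbered 1 without replicate 1. The list's adjusted p was 0.00216 by camera and 0.132 with an estimated correlation.

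The acute phase genes, whose plasma proteins the liver secretes in inflammation, split. Of 30 members 10 rose, 6 fell and 14 did not pass the test (11 rose and 6 fell when adjusted over the list alone). Without replicate 1, 7 of 29 were higher and 8 lower. In the unpaired fit none passed; 5 were higher at an unadjusted p under 0.05, and limma-voom called none. Haptoglobin (Hp) rose from 1820 to 3105 CPM (log2 0.77), Apcs by 0.75 and Crp by 0.78. Chosen after their values were seen, Saa1 was at 652 and 620 CPM (log2 -0.07), Orm1 at 578 and 571 CPM (log2 -0.02) and Lcn2 at 1177 and 1178 CPM in Control and TNF; none passed either limma fit. Camera gave an upward adjusted p of 0.0225 over a median of 0.02, but 0.0539 with the block and an adjusted p of 0.518 with an estimated correlation. It was 0.627 without Control 1 and 0.281 without TNF 3.

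PPARα targets and fatty acid oxidation genes fell for the most part. Of 48 tested members 32 fell and 4 rose (34 and 4 when adjusted over the list alone), and the unpaired fit called Cyp4a10 alone. The fatty acid transporter Slc27a2 fell from 220 ± 44.0 to 126 ± 17.5 CPM (log2 -0.79, SE 0.15), lower in each of the 3 pairs. Its adjusted p in limma was 0.102 unpaired and 4.52e-09 blocked. Cyp4a14 fell by 2.26 on the log2 scale, while Cpt1a, which admits fatty acids to mitochondria, fell by 0.26. Fgf21, a fasting hormone, rose by 0.39 with the block (adjusted p 0.0436, limma) and passed in 6 of 11 alternative settings with the block. Its adjusted p in limma was 0.308 without replicate 2 and 0.106 without replicate 3. Pdk4 fell by 0.21, with a log2 of -0.085 and an adjusted p of 0.273 without replicate 2 (limma). Without replicate 3 its log2 was -0.325. The 4 higher members, the others named after their values were seen, were Acaa1a, Plin2, Acadl and Fgf21. The count of higher members was 2 without replicate 2 or replicate 3. It was 3 without a filter, with a pseudocount of 0.1 and with the deposited log2 values. For the list the unpaired camera adjusted p was 2.71e-07, and adjusted p = 0.271 with an estimated correlation. With the block these were 3.35e-12 and 0.166.

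Of 10 ketogenesis genes 6 fell and 2 rose (7 and 2 when adjusted over the list alone). Besides Cpt1a, the mitochondrial deacetylase Sirt3 fell by 0.44 and Acat1 by 0.31, and the transporter Slc16a6 rose by 0.36. Bdh1, which makes β-hydroxybutyrate, was at 10.9 ± 2.31 and 9.08 ± 3.00 CPM, with an adjusted p of 0.930 unpaired and 0.0681 blocked in limma. The count of higher members was 1 without replicate 2 or replicate 3. It was also 1 without a filter, with a pseudocount of 0.1 and with the deposited log2 values. For ketogenesis genes camera gave an adjusted p of 0.00686, and 0.260 with an estimated correlation.

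Glucocorticoid receptor targets fell in part. Of 27 tested members 12 fell, 1 rose and 14 did not pass (15 fell and 1 rose when adjusted over the list alone). Igfbp1 fell from 588 ± 155 to 242 ± 75.4 CPM (log2 -1.30), Sgk1 by 0.93, Fkbp5 by 0.43 and Tsc22d3 by 0.34. Tat (log2 -0.19) and Pck1 (log2 -0.18) had blocked adjusted p of 0.0713 and 0.449 in limma. Over 11 alternative settings with the block Tat passed in 2, without replicate 1 or 3, and its log2 lay between -0.284 and -0.032; Pck1 passed in 1, without replicate 1, and lay between -0.404 and 0.131. In the unpaired fit none passed, 8 were lower at an unadjusted p under 0.05, and limma-voom called none. The list had an adjusted p of 0.000100 by camera, and 0.260 with an estimated correlation. The receptor genes themselves did not pass in either fit: Nr3c1 was at 104 ± 13.6 and 99.2 ± 14.1 CPM and Ppara at 118 ± 17.8 and 125 ± 19.5 CPM.

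Gluconeogenesis and amino acid catabolism genes fell in 15 of 27 cases and rose in 1 (16 and 2 when adjusted over the list alone). Cps1, the first enzyme of the urea cycle, fell from 1975 ± 794 to 737 ± 306 CPM (log2 -1.43), the glucose-6-phosphatase gene G6pc by 1.01, the histidine-degrading Hal by 0.77 and the glucose-6-phosphate transporter Slc37a4 by 0.78. The higher member was not called without replicate 3. Camera gave an adjusted p of 2.62e-06, and 0.0635 with an estimated correlation. Bile acid synthesis and transport genes fell in 14 of 22 cases and rose in 1 (16 and 1 when adjusted over the list alone), with 3 lower in the unpaired fit. Besides Cyp8b1, Abcg5 and Abcg8, the bile acid receptor gene Nr1h4 fell by 0.53; 2 members were higher without replicate 1. Cyp7a1 had 11, 11 and 5 reads in Control and 1, 3 and 3 in TNF and was not tested. The bile acid list had a camera adjusted p of 7.36e-07, and adjusted p = 0.142 with an estimated correlation.

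Cytochrome P450 and xenobiotic metabolism genes fell in 19 of 33 cases and rose in 0, against 1 higher at an unadjusted p under 0.05 and 0 by limma-voom (20 fell when adjusted over the list alone). The nuclear receptor genes Nr1i3 (CAR) and Nr1i2 (PXR) fell by 1.33 and 0.51, Fmo5 by 0.69 and Adh1 by 0.51. Camera gave an unpaired adjusted p of 3.76e-05, and 0.260 with an estimated correlation. With the block these were 5.95e-10 and 0.166. Of 31 hepatocyte transcription factors 16 fell and 1 rose, with the same counts when adjusted over the list alone. Hnf4a fell from 565 ± 54.2 to 418 ± 36.1 CPM (log2 -0.43) and Rxra by 0.42. For transcription factors the camera adjusted p was 1.09e-06, and 0.260 with an estimated correlation. None of 17 nuclear receptor coregulators passed the blocked or the unpaired limma fit or limma-voom, Ncor1 included (282 ± 27.1 and 280 ± 19.9 CPM), and 3 were lower at an unadjusted p under 0.05 in the blocked fit and 0 in the unpaired fit. Camera gave an adjusted p of 0.775 for the coregulators.

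Hepatocyte secretory and marker genes fell in 10 of 25 cases and rose in 1 (13 and 1 when adjusted over the list alone). Ahsg fell by 0.60 and Apoc3 by 0.24. Camera gave an unpaired adjusted p of 0.0152, and 0.565 with an estimated correlation. With the block camera gave 4.999e-06, and 0.227 with an estimated correlation. The unpaired value was 0.307 without Control 3 and 0.248 without TNF 1.

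**Figure D2:**
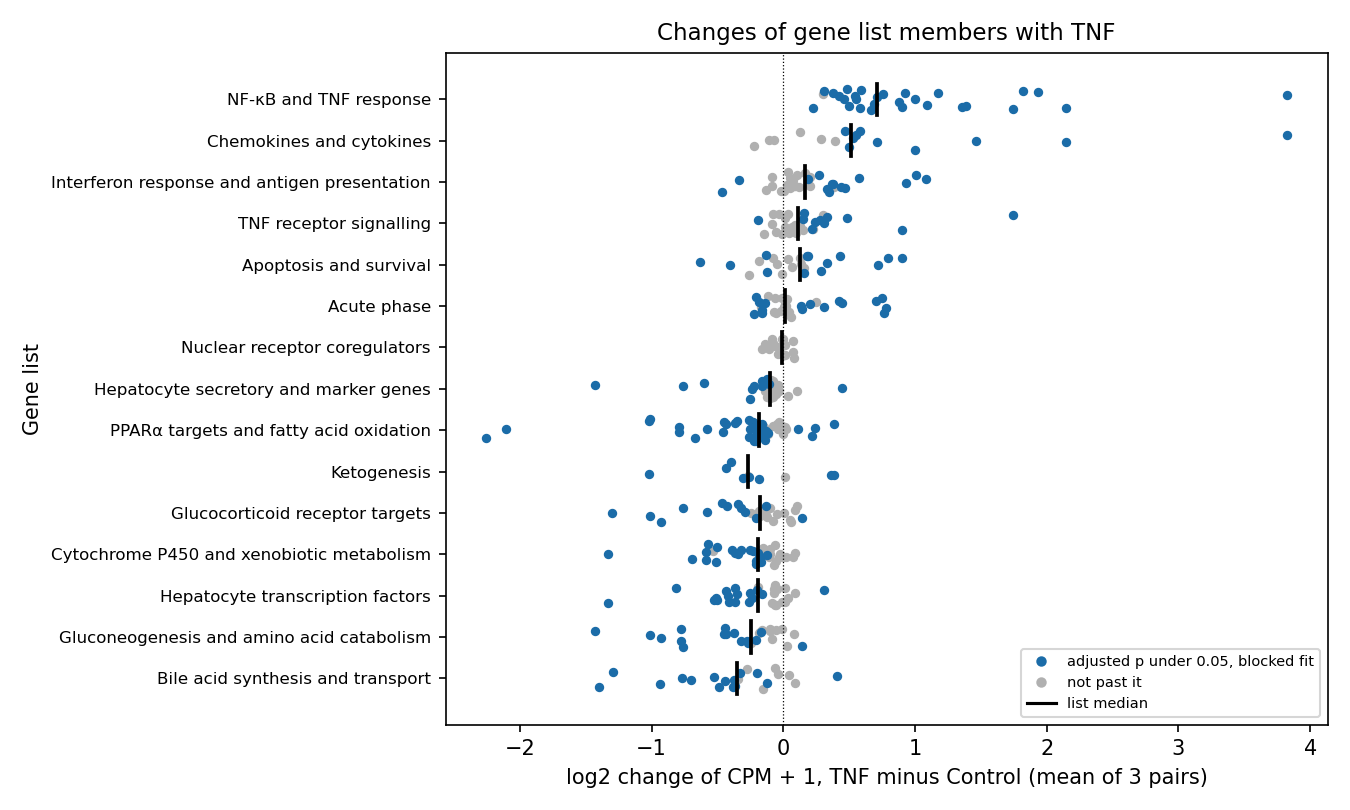
Each point is a tested member of a list, with its log2 change of CPM + 1 (TNF minus Control, mean of 3 pairs) on the horizontal axis. Blue points passed an adjusted p of 0.05 in the blocked limma fit, grey points did not, and black bars are list medians, 0.71 for the NF-κB list and -0.35 for the bile acid list.

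Few markers of other liver cells passed the test. Summed over each list, macrophage markers were at 341 ± 20.3 and 350 ± 25.3 CPM in Control and TNF, endothelial markers at 157 ± 52.7 and 169 ± 48.0, stellate markers at 70.9 ± 27.2 and 56.9 ± 13.3, cholangiocyte markers at 146 ± 53.3 and 162 ± 49.5, and lymphocyte and neutrophil markers at 0.711 ± 0.445 and 0.446 ± 0.154 CPM. Most of the macrophage sum came from Cd68 (179.7 CPM in Control and 178.8 in TNF) and Slc40a1 (150 and 157.5). Only 3 of 18 macrophage markers were tested, so this sum says little of the others. Reln (45.3 and 31.2 CPM) made up most of the stellate sum. The endothelial sum changed by a mean log2 of 0.12 ± 0.11 (SD, 3 pairs). Among 16 tested endothelial markers Stab1 (0.87) and Oit3 (0.54) rose and 1 fell, a call lost whichever replicate number was left out; Stab1 overlaps Nt5dc2. None of the 3 tested macrophage markers passed either limma fit or limma-voom (1 was higher at an unadjusted p under 0.05 with the block), and none of the 20 lymphocyte and neutrophil markers was tested. Of 8 stellate markers Reln fell (log2 -0.38), not called without replicate 2 (adjusted p 0.222, limma) or replicate 3 (0.139). Of 5 cholangiocyte markers Sox9 rose (0.58) and Pkhd1 fell (-0.31), the second with an adjusted p of 0.0915 without replicate 1 and 0.0943 without replicate 2 (limma). Camera gave adjusted p of 0.528, 0.775 and 0.587 for the endothelial, stellate and cholangiocyte lists. The endothelial list reached 0.00186, upward, without Control 3, and its direction was down without Control 1, Control 2 or TNF 3 (adjusted p 0.627, 0.909 and 0.230).

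The authors' deposited table listed 2999 genes at an adjusted p under 0.05, 1354 higher and 1645 lower. Of the 2530 genes past the blocked fit 2466 were among them, each with the same sign, as were all 53 of the unpaired calls.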

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

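Alternatives beyond those fixed in advance (the block combined with other settings, and the deposited log2 values) were chosen after seeing the data. The planned quasi-likelihood and Wald count tests and the intron comparisons were not run. With the replicate block the unpaired 53 genes became 2530 (1156 higher, 1374 lower), and limma-voom with the block gave 2520 (1156 and 1364). Without a filter the unpaired fit called 31 (28 and 3), with more genes tested. Leaving out a library gave 9 to 31 genes (8 to 26 higher, 0 to 5 lower), with fewer samples; at 0 lower, without Control 2 or 3, limma had 307 and 490 lower at an unadjusted p under 0.05 and limma-voom called 0. Other scalings, the filter at 1 CPM, both pseudocounts, the deposited values and voom gave 46 to 56. In the blocked fit no filter left 911 lower, leaving out a pair gave 1742 to 2315 genes (907 to 1224 lower), and a fold change of 1.5 or more left 280 (160 and 120). Of 16 lists called by camera, 2 were called with an estimated correlation, 5 by fry, and 0 with an estimated correlation and the block (6 at an unadjusted p under 0.05, and 12 by fry with the block). Adjusted p in those 3 settings was 0.271, 0.212 and 0.166 for PPARα targets, 0.260, 0.212 and 0.319 for GR targets, 0.260, 0.137 and 0.286 for ketogenesis and 0.518, 0.552 and 0.640 for acute phase genes. GR targets reached 0.102 and acute phase genes 0.204 by fry with the block. The NF-κB list reached 0.166 with an estimated correlation and the block. Lists with an estimated correlation below the preset weakened too: apoptosis genes (-0.031) went from 0.00216 to 0.132 unpaired. The loss of calls under this option is thus not a measure of correlation alone. Acute phase genes reached 0.0539 with the block alone, and between 0.000217 and 0.627 with a library left out. Causes were not tested. Of 116 named genes 66 passed with the block only, and no direction past a threshold turned. Scalings moved the median of all genes by at most 0.00954 (log2).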

Other observations

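The tests of the hepatocyte share of RNA, of scaling, of exchanged libraries and of endothelial cells (its bound included) were chosen after the results they measure were seen. Of 16 NRF2 targets, which serve antioxidant defence, 9 rose and 3 fell with the block (11 and 3 when adjusted over the list alone), with Hmox1 going from 380 ± 63.0 to 565 ± 166 CPM (log2 0.54) and Txnrd1 up by 0.29 and Ephx1 at -0.20. Camera gave an adjusted p of 0.0518 unpaired and 0.000112 with the block, and adjusted p of 0.737 and 0.462 with an estimated correlation. Unpaired, it was 6.86e-06 without Control 1 and 0.00213 without TNF 3, but 0.596 without Control 3 and 0.693 without TNF 1. Of 22 immediate early and heat shock genes 6 rose and 1 fell (6 and 1 when adjusted over the list alone), the risers including Junb (0.72), Egr1 (0.69), Fosl1 (0.72) and Ier3 (0.76). That list's adjusted p was 0.0365, and 0.518 with an estimated correlation; it was 0.465 without Control 1, 0.0595 without TNF 2 and 0.0906 without TNF 3.

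Of 25 unfolded protein and stress response genes 9 rose and 4 fell (10 and 5 when adjusted over the list alone; 1 lower without replicate 1); Herpud1 fell from 222 ± 46.3 to 146 ± 29.3 CPM and Pdia4 rose by 0.19. The list's adjusted p was 0.125, but 0.0441 without Control 2 and 0.0207 without TNF 1. Of 32 lipogenesis and cholesterol synthesis genes 4 rose and 7 fell (5 and 7 when adjusted over the list alone), with Elovl6 up by 0.50 and Mvk at -0.32 (camera adjusted p 0.959). Of 30 oxidative phosphorylation genes 6 fell (9 when adjusted over the list alone), a count of 1 under median-of-ratios scaling, 2 under total count scaling and 1, 0 and 2 without replicate 1, 2 and 3. Camera gave that list an adjusted p of 0.00878, and 0.727 with an estimated correlation; it was 0.141 without Control 1, 0.0912 without Control 2 and 0.874 without TNF 3. Of 18 proliferation genes Mcm3 rose and Cdk1 fell, and neither passed when adjusted over the list alone (camera adjusted p 0.978). Without replicate 1, 0 of 20 tested members were higher and 3 lower. In limma with the block the adjusted p of Cdk1 was 0.0884, 0.114 and 0.121 without replicate 1, 2 and 3, and that of Mcm3 was 0.0697 without replicate 1 and 0.103 without replicate 3.

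Genes that fell by 1.5-fold or more with the block numbered 120. A lower share of hepatocyte RNA in the TNF libraries would lower hepatocyte markers alike, but the 22 markers in no other list had a median log2 change of -0.10 (SD 0.14), against -0.58 for a 1.5-fold fall. Scaling of the libraries moves all genes alike. The other tested genes had a median log2 change of -0.0045 (SD 0.20) under total count scaling, so the 120 genes fell relative to them. That scaling sets the library totals equal, which tends to hold this median near 0. The value therefore cannot decide on a scaling error, which stays open. A change in RNA per cell was not measured and stays open. Reads shared among the Cyp4a genes were not tested and stay open for these members, as does a response to TNF for all.

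Several acute phase genes did not rise. Reads shared between paralogs could hide a change, but the summed reads of Saa1, Saa2 and Saa3 changed by a mean log2 of -0.054 (SD 0.09, 3 pairs), and those of Orm1, Orm2 and Orm3 by -0.014 (SD 0.07). A high level before TNF that limits the rise stays open, since control level and change had a Spearman rho of 0.015 across 30 genes (permutation p 0.936, two-sided), and genes are not independent replicates. No biological explanation was tested.

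Same-numbered libraries deviated together, and 6571 genes differed between the numbers. An exchange of TNF and control libraries within a pair was argued against, since the lowest of the 3 per-pair medians of the NF-κB list was 0.69 (SE 0.12). Dilution of the number 1 libraries by endothelial cells was argued against by number 3 alone. Their summed markers in number 1 differed by a mean log2 of -0.75 from number 3. The difference from number 2 was -0.061, within the bound of 0.11. That bound is the SD of the sum's changes with TNF over 3 pairs, not a spread of the differences between numbers. In number 1, 2 of 16 markers were higher than in the others. An endothelial difference of number 3 itself (217 and 224 CPM, against 120 to 142) was not tested and stays open. A difference in oxygen-responsive genes may contribute: 14 such genes, not examined before, were lower in number 1 (median log2 -0.56; camera p 1.35e-13, but 0.105 with an estimated correlation). The labels give no batch. In number 1 the NRF2 list was higher for 16 of 16 genes (median 0.54, camera adjusted p 2.98e-10, and 0.291 with an estimated correlation). Cholangiocyte markers were higher for 4 of 5 (camera adjusted p 0.0436, and 0.408), with sums of 208 and 216 CPM against 110 to 150. In Control 1, Sox9, Pkhd1, Spp1 and Epcam were at 21.5, 13.6, 8.73 and 1.11 CPM, so most of that sum lay outside these genes. Hepatocyte secretory and marker genes were lower, with 3 of 25 higher (median -0.26, camera adjusted p 0.000319). Cytochrome P450, PPARα and acute phase lists were lower too (camera adjusted p 0.000416, 0.0005855 and 0.0005855). No list passed with an estimated correlation.

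The unpaired fit called 53 genes for the real grouping and at most 0 for the other splits, and 1 of the 10 splits of the 6 libraries, the real split, reached 53. Of 4 splits that part all 3 pairs, 1 reached the blocked count of 2530, the real split, and the highest other gave 0. The other splits of that kind exchange Control and TNF within a pair. Neither 10 nor 4 splits are enough for a share under 0.05.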
